A study of Homo sapiens with 14 samples.

How the data were processed

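RNA was measured in human blood T cells that were kept in culture and treated with actinomycin D, an inhibitor of transcription, for 0, 15, 60 or 120 min. Each time point had 3 libraries, 12 in all, and the labels describe poly(A) RNA. A pair of deposited tables of counts per gene, whole numbers with no normalization, each held 12 columns named for these 12 samples. Whether both tables come from the same libraries is not given in the sources used here, and a test described in the closing section argues against the same reads. The submitters' processing notes name cutadapt, TopHat, HTSeq, edgeR and the hg19 build, without the role of each tool. The first table itself names no build, and hg19 was taken as its build because the other table is named for hg38. The second table was deposited as counts from featureCounts on hg38, per its own name, and the series text says that reads were mapped to both builds. The aligner of the second table, the annotations and all tool versions are not given in the sources used here. Whether the counting used strand is not given either, so genes that overlap on opposite strands may share counts.

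The first table was used for all results unless the second is named, because the build taken for it is the one in the processing notes. This order was chosen before the data were examined, as were the tests, the 27 gene lists and the alternatives, except where a later choice is stated. The first table held 24405 genes and the second 26085, of which 23149 were in both. Y-linked genes, XIST and TSIX (69 and 71 entries) were left out of every step. Symbols were matched to GENCODE release 44 mapped to GRCh37, with older symbols looked up in RefSeq synonyms, for 22165 and 23580 genes; coordinates in the text are from that annotation. Another table holds 2 nanopore direct RNA libraries, a control and a METTL3 knockdown. Its 4 columns of values per sample are all headed as the control, so no column could be tied to the knockdown by name, and that table is not used here.

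Library totals in the first table, in units of 1e6 counts, ranged from 12.3 to 19.5 (14.8 ± 2.15, mean ± SD, n = 12), with 14353 to 14956 genes detected. Totals in the second table ranged from 24.4 to 42.1 in the same units. Counts of every pair of replicates of a time point differed by far more than sampling noise (chi-square per gene from 29.5 to 72.8 in the first table), so no library was counted as a copy of another. The labels do not say whether replicates came from separate donors or cultures, so p-values measure only the spread between these samples, which may be technical.

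Genes were filtered with filterByExpr by time group, which left 12426 in the first table and 14806 in the second. Libraries were scaled by the trimmed mean of M values (TMM). Changes were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) on the deposited counts, with all 12 libraries in one fit so that the 4 time points shared one estimate of the spread, and with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Contrasts compared 15, 60 and 120 min with 0 min, and the change from 60 to 120 min with that from 0 to 60 min. A second fit took time in hours as a number and gave a log2 change per hour. No spike-in is named in the labels, so each change is relative to the typical transcript of the same libraries. Levels are counts per 1e6 counts (CPM) on TMM-scaled totals, and fold changes carry the standard error (SE) of the fit.

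Gene lists with at least 5 measured genes were tested at 120 min with camera of limma 3.58.1 (preset correlation 0.01, two-sided), adjusted over the lists; camera with an estimated correlation and fry were alternatives. Slopes of the lists of T cell identity and of housekeeping genes were compared by the difference of medians, with a two-sided permutation test over genes (100000 resamples) and a 95% bootstrap interval. Genes are not independent replicates, so these p-values describe the lists. Random lists (10000 per test) were matched on mean expression, transcript length and, for slopes, GC content, from the 50 nearest genes of each member.

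The text names genes by a rule set before the data were examined. For each time point it took the 10 largest decreases and 10 largest increases among called genes with mean log2 CPM of at least 3 and with all 3 libraries on one side of all 3 at 0 min. For slopes it took the 10 largest each way without that separation, for the difference between intervals the 10 largest, and for each list the 4 members with the lowest adjusted p at 120 min. The members named from each list are a subset of those 4, picked after their values were seen. Some genes that met the rule are not reported here.

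The replicate numbers were checked as pairs across time points from each library's deviations from its time point mean. In the first table libraries with the same number correlated at 0.557 to 0.715 and those with other numbers at -0.453 to -0.125; in the second table the ranges were 0.364 to 0.585 and -0.358 to -0.0204. All 12 libraries correlated best with their own number in each table. The numbers therefore pair the libraries by the data, not by any label, and a fit with the replicate number as a block was run as an alternative.

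The fits were tested on simulated counts in which 200 genes were changed. Of genes changed 2-fold, 37%, 38% and 31% were recovered at 15, 60 and 120 min, and of genes changed 4-fold 91%, 92% and 94%, with 6, 5 and 4 false calls among 12287 genes. For slopes 57% and 93% were recovered with 13 false calls among 12289 genes, and for the difference between intervals 2% and 52% with 6 false calls among 12287. A simulated changed list was called (camera adjusted p = 3.4e-09) and 0 unchanged lists were called. Each gene was simulated independently of the others, so this check could not show false list calls that arise from correlation between genes.

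Alternatives were DESeq2 1.42.0, its median-of-ratios size factors within edgeR, library totals alone, scaling to the summed counts of ribosomal protein genes, no filter, a mean of at least 5 CPM, the replicate block, only the 6 libraries of a comparison, the second table, and leaving out each library or replicate number in turn.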

Results

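Human blood T cells were sampled at 0, 15, 60 and 120 min of actinomycin D, with 3 libraries per time point. Actinomycin D stops new transcription, so RNA present at the start is lost at the rate at which each transcript decays. The series title asks whether RNA of cell identity genes is less stable than other RNA. All values are relative to the typical transcript: a gene above 0 on the log2 scale fell less or rose more than the typical transcript, which does not mean that more of its RNA was made. Ribosomal protein genes took 2.95 ± 0.132% of counts at 0 min and 5.82 ± 0.649% at 120 min (mean ± SD, n = 3).

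After 15 min the genes that fell included the cytokine genes OSM and TNF, the signalling inhibitor SOCS3 and the transcription factor KLF2. OSM, the cytokine oncostatin M (chromosome 22, 30658818 to 30662840, minus strand), fell by 2.56 ± 0.36 on the log2 scale (SE), from 196 ± 80.5 to 33.2 ± 14.7 CPM (SD, n = 3). SOCS3, an inhibitor of JAK-STAT signalling (chromosome 17, 76352859 to 76356158, minus strand), fell by 2.01 ± 0.19, and the cytokine TNF by 2.00 ± 0.29. PDE4B, a phosphodiesterase that breaks down cyclic AMP, fell by 2.02 ± 0.30, and KLF2, a transcription factor of T cell quiescence, by 1.49 ± 0.21. The other named genes were MED26 (-1.84), a Mediator subunit, ARID5B (-1.75), ARRDC3 (-1.63), ZFP36L2 (-1.58), which binds AU-rich elements and promotes decay, and ZNF217 (-1.53). Adjusted p ranged from 0.00376 for SOCS3 to 0.0180 for PDE4B in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In total 29 of 12426 genes fell and 0 rose in that test, with 683 genes at an unadjusted p under 0.05. Scaling to ribosomal protein counts gave 65 lower and 0 higher, DESeq2 125 and 2, and the replicate block 408 and 76. Of the immediate early list, 8 of 47 members fell, as did 2 of 29 cytokines and chemokines and 2 of 24 checkpoint and feedback genes. Adjusted over the list alone these were 30, 2 and 5, with 5 KRAB zinc finger genes, 3 T lineage transcription factors and 2 targets of p53 lower as well. The count of 29 fell to 0 without the 15 min library of replicate 1 or of replicate 3, and to 0 without replicate 2 or replicate 3 at all times. It was 1, 3 and 12 without the 0 min libraries of replicates 3, 2 and 1, 17 without the 15 min library of replicate 2 and 11 without replicate 1, and the second table had 0 lower and 1 higher (50 and 22 with the block). None of the 10 named genes was called there without the block (SOCS3 -0.99, MED26 -0.39), and MED26, KLF2 and ZFP36L2 were not called with it. With only the 6 libraries compared, OSM at 15 min had an adjusted p of 0.0565.

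By 60 min the genes that fell included the signalling inhibitor CISH and the transcription factors MYC and KLF2. CISH, an inhibitor of cytokine signalling (chromosome 3, 50643920 to 50649205, minus strand), fell by 4.57 ± 0.22 on the log2 scale, from 990 ± 162 to 41.8 CPM (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 5.9e-07). MYC, a transcription factor of growth (chromosome 8, 128747680 to 128755197, plus strand), fell by 3.69 ± 0.20, and KLF2 (chromosome 19, 16435637 to 16439496, plus strand) by 3.93 ± 0.24. The other large decreases were OSM (-4.15), CSRNP1 (-3.95), MED26 (-3.89), TIPARP (-3.83), RHOH (-3.73), PDE4B (-3.72) and PPM1D (-3.70). TIPARP is a mono-ADP-ribosyltransferase and PPM1D a phosphatase of the p53 response. Among genes that rose relative to the typical transcript were the ribosomal protein genes RPS10 (1.58 ± 0.31), RPS7 (1.52 ± 0.36) and RPL7 (1.51 ± 0.24), the pseudogene RPL23P8 (1.47) and RMRP (1.47), the RNA of a nuclease complex. The rest were MIR3648 (2.71 ± 0.48), LINC01089 (1.36), SAP25 (1.35), MYO15B (1.34) and SCNN1D (1.34). Ribosomal protein genes share sequence with many pseudogenes and MIR3648 lies in repeated ribosomal DNA, so their counts are uncertain. Of the lists, 38 of 47 immediate early genes, 45 of 80 KRAB zinc finger genes and 17 of 33 T lineage transcription factors fell, and 66 of 72 ribosomal protein genes rose. Adjusted over the list alone these were 39, 54, 19 and 67, with 1 ribosomal protein gene lower.

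In total 1848 genes fell and 1078 rose at 60 min, with 1054 and 110 of them by over 2-fold, and the replicate block called 3032 and 2927. Scaling set the balance: library totals gave 2317 lower and 520 higher, and scaling to ribosomal protein counts, which moved the median gene to -0.75, gave 6780 and 14. The second table called 395 lower and 28 higher, and 1510 and 854 with the replicate block. Without the block MED26 at 60 min lay at -0.60 there (adjusted p = 0.438), and RPL7, RPS7, RMRP, LINC01089, SAP25, MYO15B and SCNN1D were not called, while MIR3648, RPS10 and RPL23P8 were not among the genes tested there. With the block RPS7, RMRP, SAP25, MYO15B and SCNN1D were still not called there. Without replicate 2 at all times 714 genes fell and 136 rose, without replicate 3 1200 and 328, and without replicate 1 689 rose. The higher count was 602 and 559 without the 0 min libraries of replicates 1 and 2, and 663, 712 and 689 without the 60 min libraries of replicates 1, 2 and 3. The calls of RPS10 at 60 min (adjusted p = 0.0789), RPL7 at 60 min (0.0580), MIR3648 at 60 min (0.0526) and MYO15B at 60 min (0.0873) were lost without replicate 2, and that of RPS7 at 60 min (0.0567) without replicate 3. The call of SAP25 at 60 min was lost without replicate 2 (0.139), replicate 3 (0.0654), the 0 min library of replicate 2 (0.0657) or the 60 min library of replicate 1 (0.0649). The call of LINC01089 at 60 min was lost in 7 of the 15 fits that left out samples, with adjusted p up to 0.198 without replicate 2.

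At 120 min the largest decreases included the signalling inhibitors CISH and DUSP5 and the receptor TNFRSF1A. CISH fell by 5.29 ± 0.23 on the log2 scale, to 25.2 ± 3.30 CPM (n = 3; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 8.9e-08). DUSP5, a phosphatase that inactivates ERK (chromosome 10, 112257665 to 112271291, plus strand), fell by 4.75 ± 0.30, and TNFRSF1A, a receptor of TNF (chromosome 12, 6437923 to 6451280, minus strand), by 4.17 ± 0.28. PDE4B (-4.35), CSRNP1 (-4.23), KLF2 (-4.20), HPS6 (-4.14), PPM1D (-4.00), RHOH (-3.99) and SLA (-3.93), an adaptor that dampens T cell receptor signalling, completed the 10. The same 10 genes were called in the second table with smaller decreases, for example CISH at -2.88, DUSP5 at -2.27, TNFRSF1A at -1.95 and PPM1D at -1.39. Relative increases were led by MIR3648 (2.97 ± 0.49), RPL7 (2.57 ± 0.25), RPS10 (2.52 ± 0.32) and MUC2 (2.20 ± 0.63). RPL23P8 (2.13), the snoRNA host gene SNHG9 (2.11; chromosome 16, 2014896 to 2015510, plus strand), RPL28 (1.99), RPS7 (1.93) and ATP5J2 (1.85), a subunit of ATP synthase, followed. The call of MUC2 at 120 min was lost without the 0 min library of replicate 2 (adjusted p = 0.0508), without replicate 1 (0.134) and without replicate 3 (0.129).

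In total 3032 genes fell and 2425 rose at 120 min, 1930 and 704 of them by over 2-fold; the replicate block called 3908 higher. Library totals gave 4299 lower and 1104 higher, and scaling to ribosomal protein counts, which moved the median gene to -1.27, gave 9159 and 13. Without replicate 2 at all times 1292 genes rose, and without replicate 3 1566. The second table called 1195 lower and 249 higher, and 2575 and 2288 with the replicate block. Of the relative increases named, RPL7, SNHG9, RPL28, RPS7 and ATP5J2 were not called there without the block, and SNHG9 was not called with it either; MIR3648, RPS10, MUC2 and RPL23P8 were not among the genes tested there. Of 12022 genes in both tables, 3004 fell in the first and 93.3% of these lay below 0 in the second, 2356 rose and 97.1% of these lay above 0, and 3 genes were called in opposite directions.

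**Figure D1:**
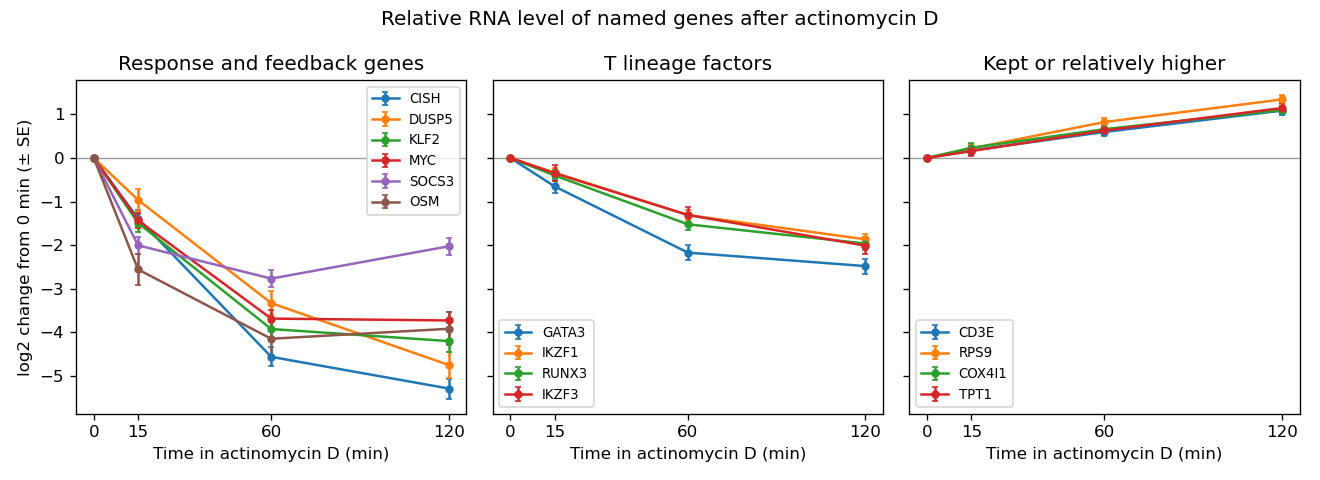
Log2 change in relative RNA level from 0 min (vertical axis) against minutes in actinomycin D (horizontal axis) for named genes in the first table; points are fitted values from 3 libraries per time point and bars are ± SE. CISH reached -5.29 and GATA3 -2.48 at 120 min while CD3E reached 1.09; with scaling to ribosomal protein counts CD3E, COX4I1 and TPT1 lay below 0.

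T lineage transcription factors, which set and keep T cell identity, fell as a group at 120 min: 22 of 33 fell and 2 rose (26 and 2 adjusted over the list alone), with a median log2 change of -1.17. GATA3 fell by 2.48 ± 0.17 on the log2 scale, from 297 ± 44.9 to 53.2 ± 8.24 CPM. IKZF1 (-1.87 ± 0.11), RUNX3 (-1.96 ± 0.14) and IKZF3 (-2.01 ± 0.19) fell too. Camera gave the list an adjusted p of 1.2e-06, and 0.0400 with an estimated correlation, which became 0.0901 with the replicate block. In the second table the list lay lower too (median -0.50, camera adjusted p = 1.7e-04, and 0.199 with an estimated correlation, or 0.0739 with the block as well), though GATA3 lay at -0.61 with an adjusted p of 0.201 and IKZF3 at -0.70 with 0.0673 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With the block both were called there (adjusted p = 0.00281 for GATA3 at 120 min and 1.0e-05 for IKZF3 at 120 min).

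Surface and signalling genes of T cells moved both ways: 15 of 40 fell and 11 rose (15 and 12 adjusted over the list alone). CD3E, a chain of the T cell receptor complex, rose by 1.09 ± 0.10 relative to the typical transcript. THEMIS (-1.32 ± 0.10), the adaptor GRAP2 (-1.25 ± 0.13) and the kinase PRKCQ (-1.24 ± 0.14) fell. The list's median was 0.10, its mean -0.20, and the direction of the camera test was down with an adjusted p of 0.923; fry, which tests the list without other genes, gave an adjusted p of 0.00912. With scaling to ribosomal protein counts CD3E lay at -0.21, and in the second table THEMIS at 120 min lay at -0.15 (adjusted p = 0.594, and 0.345 with the block). Broadly expressed transcription factors fell in 16 of 35 and rose in 4 (the same numbers adjusted over the list alone, median -0.33). CTCF, an architectural factor (-2.96 ± 0.15), NRF1 (-2.85 ± 0.22) and NFE2L2 (-2.34 ± 0.18) were among those that fell. Camera gave that list an adjusted p of 0.00974, with 0.0660 for an estimated correlation and 0.242 in the second table.

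Immediate early genes fell as a group. Of the immediate early list 38 of 47 fell and 1 rose (40 and 1 adjusted over the list alone, median -2.02), with a camera adjusted p of 1.5e-13, and of 0.0383 with an estimated correlation, which became 0.0901 with the replicate block. NFKBIA, the inhibitor of NF-kappaB (-3.77 ± 0.18), MYC (-3.73 ± 0.20) and the activation marker CD69 (-3.16 ± 0.17) were examples. Checkpoint and feedback genes fell in 11 of 24 and rose in 2 (the same adjusted over the list alone, median -0.85, camera adjusted p = 0.0130, and 0.113 with an estimated correlation), among them SOCS1 (-3.43 ± 0.43) and SOCS3 (-2.03 ± 0.20). Cytokines and chemokines fell in 8 of 29 and rose in 3 (the same adjusted over the list alone, median -0.32). Their share lower was near the 24.4% of all tested genes that fell, and camera did not call the list (adjusted p = 0.334). OSM, TNFSF14 (-3.52 ± 0.27) and TNF (-2.23 ± 0.29) were among those that fell. Fry gave the list an adjusted p of 0.00558. In the second table camera gave an adjusted p of 0.00349, with 0.199 for an estimated correlation and 0.0344 with the block as well. KRAB zinc finger genes, repressors of transposable elements, fell in 51 of 80 and rose in 0 (58 and 0 adjusted over the list alone, median -1.32, camera adjusted p = 6.1e-11, and 0.163 with an estimated correlation). ZNF317 fell by 2.44 ± 0.16 and ZNF263 by 1.96 ± 0.15. Targets of p53 fell in 13 of 25 and rose in 2 (the same adjusted over the list alone, median -0.95, camera adjusted p = 0.0212, and 0.530 with an estimated correlation), with SESN2 at -3.17 ± 0.47, CDKN1A at -1.46 ± 0.13 and FAS at -0.95 ± 0.12. FAS at 120 min was not called in the second table (adjusted p = 0.128) and was with the block (0.0212). With scaling to ribosomal protein counts the list p53_target at 120 min (adjusted p = 0.163) and the list Checkpoint_feedback at 120 min (0.0654) were not called. Camera with the block and an estimated correlation called, in the second table, the immediate early (adjusted p = 0.0398), KRAB (0.0381) and p53 (0.0381) lists. Without the block these were 0.0671, 0.0671 and 0.425 there, and with it 0.0901 for each in the first table.

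Genes of RNA modification and decay were themselves among those that fell. Of the m6A machinery, which writes, removes and reads the methyl mark on RNA, 13 of 21 fell and 2 rose (the same adjusted over the list alone, median -0.98). The readers YTHDF2 (-2.66 ± 0.16) and YTHDF1 (-2.02 ± 0.13) fell, as did the writer complex genes CBLL1 (-2.23 ± 0.17) and KIAA1429 (-1.60 ± 0.15). Camera gave an adjusted p of 0.00161, and 0.0400 with an estimated correlation, which became 0.0901 with the replicate block. The RNA decay and microRNA machinery fell in 25 of 60 and rose in 4 (the same adjusted over the list alone, median -0.26), including CNOT4 (-2.83 ± 0.20), DCP1B (-2.49 ± 0.21) and TOB2 (-2.24 ± 0.16). Its camera adjusted p was 0.00171, 0.193 with an estimated correlation and 0.201 in the second table.

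Genes of protein synthesis and energy metabolism were kept relative to the typical transcript. Ribosomal protein genes rose in 69 of 72 and fell in 0 (70 and 0 adjusted over the list alone, median 1.30), with RPS9 at 1.34 ± 0.10 and RPL13A at 1.28 ± 0.10; camera gave an adjusted p of 3.8e-30, and 0.0862 with an estimated correlation. Nuclear genes of oxidative phosphorylation rose in 58 of 68 and fell in 0 (the same adjusted over the list alone, median 0.93, camera adjusted p = 4.4e-17, and 0.163 with an estimated correlation), such as COX4I1 (1.10 ± 0.10) and NDUFA1 (1.15 ± 0.11). Housekeeping genes rose in 23 of 34 and fell in 2 (25 and 2 adjusted over the list alone, median 0.73, camera adjusted p = 1.6e-05, and 0.121 with an estimated correlation). TPT1 rose by 1.15 ± 0.11, EEF1A1 by 1.27 ± 0.16 and CHMP2A by 0.91 ± 0.11. With scaling to ribosomal protein counts the medians were -0.37 for oxidative phosphorylation and -0.57 for housekeeping genes, and the camera adjusted p of the latter was 0.311. Camera with the block and an estimated correlation gave, in the second table, an adjusted p of 0.0344 for ribosomal protein and for housekeeping genes. Without the block these were 0.289 and 0.408 there, and with it 0.0901 and 0.0980 in the first table.

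Proteasome genes rose in 19 of 33 and fell in 3 (the same adjusted over the list alone, median 0.52, camera adjusted p = 0.00539, and 0.515 with an estimated correlation), with PSMD8 at 0.69 ± 0.10 and PSMD5 at -1.06 ± 0.15; scaled to ribosomal protein counts, the list Proteasome at 120 min had a median of -0.79. Glycolysis genes rose in 11 of 21 and fell in 2 (13 and 2 adjusted over the list alone, median 0.91, camera adjusted p = 0.0219, and 0.587 with an estimated correlation). LDHB rose by 0.89 ± 0.11 and the glucose transporter SLC2A1 fell by 2.91 ± 0.31. The call of the list Glycolysis at 120 min was lost without replicate 2 (adjusted p = 0.0517), without replicate 3 (0.0683) and in fry (0.0969). Host genes of snoRNAs rose in 11 of 17 and fell in 2 (the same adjusted over the list alone, median 0.97, camera adjusted p = 0.00164, and 0.0862 with an estimated correlation), such as SNHG1 (1.56 ± 0.18), GAS5 (1.37 ± 0.19) and SNHG6 (0.97 ± 0.12). Cytotoxic granule genes rose in 4 of 15 and fell in 1 (the same adjusted over the list alone, median 0.92, camera adjusted p = 0.0218, and 0.515 with an estimated correlation), with LAMP1 at 1.02 ± 0.18 and GZMM at 0.86 ± 0.11; the call of the list Cytotoxic_granule at 120 min was lost without replicate 1 (adjusted p = 0.0511). Of the list members named from protein synthesis, metabolism, RNA decay and snoRNA hosts, TPT1, EEF1A1, RPL13A, COX4I1, NDUFA1, PSMD5, PSMD8, LDHB, GZMM, LAMP1, CBLL1, CNOT4, SNHG6 and GAS5 were not called in the second table without the block and were with it. Camera with the preset correlation called 15 lists, and from 8 to 14 in each other split of the same 6 libraries. The number of lists called with that correlation therefore does not set the real split apart.

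Other lists were not called by camera in the first table, while fry called the heat shock list (adjusted p = 0.00124). Interferon-stimulated genes fell in 12 of 46 and rose in 11 (camera adjusted p = 0.923), with IRF1 at -1.99 ± 0.31 and IFI6 at 1.51 ± 0.20. Cell cycle genes fell in 18 of 50 and rose in 10 (0.376), with CDC25A at -3.06 ± 0.37 and TTK at -2.49 ± 0.29. Heat shock genes fell in 5 of 16 and rose in 5 (0.701), with BAG3 at -2.43 ± 0.35 and DNAJB1 at -2.21 ± 0.23. These numbers were the same adjusted over the list alone. TTK at 120 min (adjusted p = 0.319), BAG3 at 120 min (0.126) and CEBPB at 120 min (0.0665) were not called in the second table and were with the block. Replication histones rose in 1 of 18 and fell in 0 (0 and 0 adjusted over the list alone; 0.0942; 0.0484 without replicate 2); 10 of 24 fell and 0 rose in the second table (median -0.89, camera adjusted p = 8.2e-12, and 0.289 with an estimated correlation). Few markers of other blood cells were called: 1 of 15 B cell genes rose (1 over the list alone; 0.372), 1 of 8 monocyte and macrophage genes rose and 1, CEBPB, fell (0 and 1 over the list alone; 0.779), and 1 of 15 NK cell genes rose (0 over the list alone; 0.228). Their medians were 0.64, 0.52 and 0.65, and for the monocyte list fry had the opposite direction. With scaling to ribosomal protein counts camera called the list B_cell at 120 min (adjusted p = 8.8e-06), the list Monocyte_macrophage at 120 min (0.00315) and the list NK_cell at 120 min (1.6e-05), and the last also in the second table with the block (0.00560, and 0.0645 with an estimated correlation). Erythroid and platelet markers (2 measured), neutrophil and dendritic cell markers (3) and mitochondrially encoded genes (0) were too few to test in the first table. The 5 neutrophil and dendritic cell markers measured in the second table gave a camera adjusted p of 0.988.

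**Figure D2:**
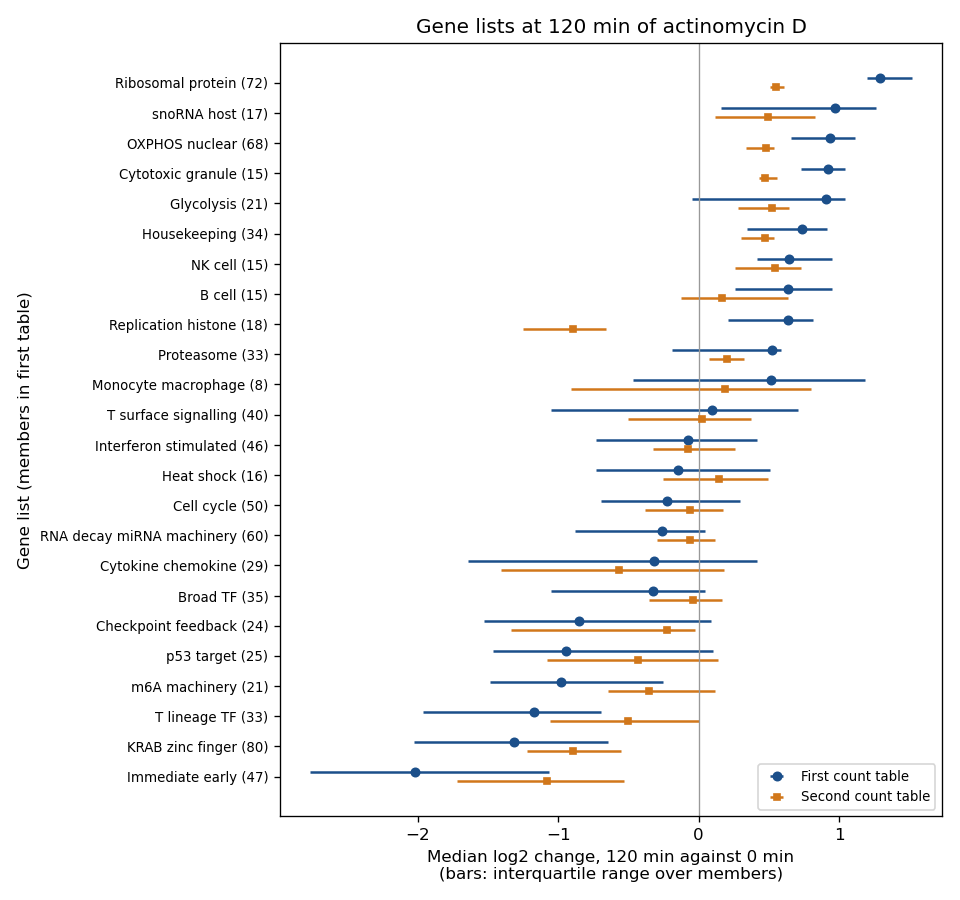
Median log2 change at 120 min against 0 min (horizontal axis) of each gene list (vertical axis, with the number of members in the first table), in the first table (circles) and the second (squares); bars are interquartile ranges over members. The first-table medians ran from -2.02 for immediate early genes to 1.30 for ribosomal protein genes; the second-table medians lay nearer 0 for most lists, and replication histones lay at -0.89; scaled to ribosomal protein counts, housekeeping genes lay at -0.57.

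Along the whole time course CISH (-2.62 ± 0.29 log2 per hour), DUSP5 (-2.44 ± 0.19) and TNFRSF1A (-2.15 ± 0.16) had the lowest slopes among genes that met the naming rule. Each passed the threshold of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 5.3e-06, 3.9e-07 and 2.3e-07). CSRNP1 (-2.13), PDE4B (-2.10), PPM1D (-2.06), HPS6 (-2.06), KLF2 (-2.03), DDX20 (-2.03) and RHOH followed. A slope takes the loss as constant over time, so it understates early loss where the loss slowed. CISH moved by -4.57 in the first hour and by -0.73 in the next. MIR3648 (1.38), MUC2 (1.34), RPS10 (1.32), RPL7 (1.25), RPL23P8 (1.07), SNHG9 (1.04), RPL28 (1.02) and RPS7 (1.00) had the largest relative gains, with PPFIA4 (1.21) and RPS28 (1.18), whose calls were lost in 4 and 9 of 15 fits that left out samples (adjusted p up to 0.0951 for PPFIA4 along time and 0.242 for RPS28 along time). The value of SNHG9 along time in the second table was -0.23 (adjusted p = 0.812, and -0.28 with the block), RPL7 (0.0513) and PPFIA4 (0.117) were not called without the block, and MIR3648, MUC2, RPS10 and RPL23P8 were not among the genes tested. In total 3295 genes fell and 2888 rose along time. Library totals gave 4732 and 1301, scaling to ribosomal protein counts gave 9628 and 18, and 1605 and 772 were called lower and higher in the second table, or 2722 and 2591 with the block.

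The study's question was addressed by setting T cell identity genes against housekeeping genes. The median slope was -0.35 log2 per hour over 73 identity genes and 0.36 over 34 housekeeping genes, a difference of -0.72 (95% bootstrap interval -0.86 to -0.48; permutation test over genes, p = 6e-05, adjusted over 5 comparisons 1.5e-04). Transcription factors and surface genes differed. T lineage transcription factors lay at -0.59, lower than housekeeping genes by 0.95 (difference -0.95, interval -1.18 to -0.71; permutation p = 1e-05, the smallest that the resamples can give, adjusted 5e-05), and 90.9% of them had a slope below 0 against 17.6% of housekeeping genes. Surface and signalling genes lay at 0.05, a difference of -0.32 from housekeeping genes (-0.71 to -0.14; permutation p = 0.00333, adjusted 0.00333). The factors lay below the surface genes (difference -0.63, -0.90 to -0.18; permutation p = 3.2e-04, adjusted 5.3e-04) and below broadly expressed transcription factors, which had a median of -0.17 (difference -0.41, -0.69 to -0.07; permutation p = 0.00302, adjusted 0.00333). In the second table identity genes lay below housekeeping genes by a difference of -0.33 (-0.46 to -0.23; permutation p = 1.5e-04, adjusted 3.8e-04).

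Early and late loss differed for 100 genes, all of which fell more from 0 to 60 min than from 60 to 120 min, and all of which were called lower at 60 min. Their median change was -2.27 on the log2 scale in the first hour and -0.17 in the next, and 16 of 47 immediate early genes were among them. MYC moved by -3.69 and then by -0.04 (difference 3.64 ± 0.34, adjusted p = 8.1e-04 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and SOCS3 by -2.77 and then by 0.74 (difference 3.51 ± 0.36, adjusted p = 9.8e-04). In the same test the MYC call was lost without replicate 2 (adjusted p = 0.0970). The SOCS3 call was lost in the second table (difference 2.13, adjusted p = 0.36) and without replicate 2 or replicate 3. The count of 100 genes became 571 with the replicate block, 281 in DESeq2 and 4 in the second table (150 with the block). It fell to 1 without replicate 2, 4 without replicate 3 and 39 without replicate 1; to 52 without the 0 min library of any replicate; and to 45, 26 and 50 without the 60 min libraries of replicates 1, 2 and 3.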

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

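The splits within replicate numbers were chosen after the result was seen. The test of the difference between the first and the second hour picked out 100 genes. The largest differences among genes with enough counts were OSM 4.38, MED26 3.99, TIPARP 3.98, CISH 3.84, PRDM1 3.69, KLF2 3.65, MYC 3.64, SOCS3 3.51, ARID5B 3.50 and RHOH 3.48 (log2 change from 60 to 120 min minus that from 0 to 60 min). They include a cytokine, feedback inhibitors and transcription factors. In the second table CISH (2.90), MYC (2.91) and RHOH (2.46) were called. The others were not, for example MED26 at 0.89, TIPARP at 1.96 and PRDM1 at 1.66. Of the others MED26 alone was still not called there with the replicate block. PRDM1, a regulator of effector T cells, changed by -3.53 in the first hour and lay 0.15 higher at 120 min than at 60 min. The count was 39 without replicate 1, 1 without replicate 2 and 4 without replicate 3. Each of these fits has 2 libraries per time point, and the differences themselves moved less: MYC lay at 3.63, 3.50 and 3.85 and CISH at 3.85, 3.83 and 3.89 (MYC interval difference and CISH interval difference).

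Of 100 splits of the 12 libraries into time points, the real one included, 2 gave at least 100 genes for this difference, the highest other 2474. These splits ignore the pairing of libraries by replicate number. Of 100 splits that reassigned times within each number, 13 gave at least 100 genes, the highest other 5150. The split with 5150 exchanged 0 and 60 min in all 3 numbers, so its contrast held the change from 0 min to the later times. The one with 2474 kept the 3 libraries of 0 min together. Because such splits still hold the effect of time, these shares cannot decide whether chance gave the 100 genes. What the other splits with many calls had in common was not examined. On simulated counts of the same size the test recovered 52% of genes with a 4-fold difference between the intervals and 2% of those with a 2-fold difference, so smaller differences were mostly not detectable at this depth and spread.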

How the results depend on the processing

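The second table with the replicate block, and ribosomal protein scaling for the identity against housekeeping difference, were chosen after seeing the data. Not run were the nanopore alternatives (other scaling, read minimums, pseudocount and numbers of fast-decaying genes), because that table is not used here. The causes of the changes listed were not tested, except that fewer samples enter each leave-one-out fit. Library totals gave 520, 1104 and 1301 genes higher at 60 min, 120 min and along time. Ribosomal protein scaling, which lowers the median gene, gave 65, 6780, 9159 and 9628 lower at 15, 60, 120 min and along time, and 14, 13 and 18 higher at the last 3. DESeq2 gave 125 lower and 2 higher at 15 min and 281 for the difference between hours.

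The replicate block gave 408 lower and 76 higher at 15 min, 3032 and 2927 at 60 min, 3908 higher at 120 min and 571 for the difference between hours; all 140 named gene values kept their side of the threshold, and so did all 24 list calls with the preset correlation. The second table gave 0 lower and 1 higher at 15 min, 395 and 28 at 60 min, 1195 and 249 at 120 min, 1605 and 772 along time, and 4 for the difference between hours. With the block it gave 50 and 22, 1510 and 854, 2575 and 2288, 2722 and 2591, and 150. A test in the closing section argues against the same reads in both tables. Differences from the second table are therefore not to be read as effects of processing alone. With an estimated correlation 3 lists were lower and 0 higher, against 8 and 7. Fry gave T cell surface genes an adjusted p of 0.00912. Housekeeping genes had an adjusted p of 0.311 with ribosomal protein scaling and 0.121 with an estimated correlation.

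With ribosomal protein scaling the log2 change at 120 min reversed for CD3E (-0.21), TPT1 (-0.15), CHMP2A (-0.39), EEF1A1 (-0.034), RPL13A (-0.023), COX4I1 (-0.21), NDUFA1 (-0.15), PSMD8 (-0.61), LDHB (-0.41), GZMM (-0.44), LAMP1 (-0.26), SNHG6 (-0.33), HIST1H2BK (-0.52), CD72 (-0.55) and NCR3 (-0.32), and for the proteasome list (camera adjusted p = 0.226). In the second table, without and with the block, HIST1H2BK (-0.59 and -0.63), SERPINB9 (0.10 and 0.097) and SNHG9 along time (-0.23 and -0.28) reversed, as did replication histones (camera adjusted p = 8.2e-12 and 4.7e-17, and 0.289 and 0.111 with an estimated correlation); SNHG9 at 120 min reversed with the block (-0.17). Of the named gene values, 57 lost the threshold in the second table and 11 in it with the block, 18 with ribosomal protein scaling, 5 with library totals and 1, OSM at 15 min (adjusted p = 0.0565), with only the 6 libraries compared; none did so with size factors of DESeq2, no filter, the filter at 5 CPM or DESeq2.

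Leaving out samples, the ranges were 0 to 35 lower and 0 to 0 higher at 15 min, 714 to 1999 and 136 to 1310 at 60 min, 2035 to 3032 and 1292 to 2430 at 120 min, 2609 to 3412 and 2124 to 2880 along time, 1 to 96 for the difference between hours, and 8 to 8 lists lower and 6 to 7 higher. Adjusted p ranged from 4.5e-07 to 9.8e-05 for housekeeping genes, 1.7e-07 to 3.4e-06 for T lineage factors and 0.825 to 0.941 for T cell surface genes. The identity against housekeeping difference in slope ranged from -0.72 to -0.67 log2 per hour when a replicate number was left out. It was -0.81 against oxidative phosphorylation, -0.71 over well-expressed members and -0.72 with the replicate block. On another scale, the log2 change over the whole 120 min, the difference was -1.46. Ribosomal protein scaling gave -0.71 log2 per hour. That scaling moves all genes of a library alike, so it could hardly change a difference between lists and is no test of it. Where an arm had 1 library fewer, the spread was taken from all time points. With 3 libraries per time point, 31% to 38% of simulated 2-fold changes were recovered. The adjusted threshold depends on how many genes change. The simulation changed 200 genes, while the data had 29 calls at 15 min and 5457 at 120 min, so these shares need not hold in the data. A gene not called may still have changed 2-fold.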

Other observations

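The tests of loss of other transcripts, of recounting by the share of genes with low counts, and of RNA without a poly(A) tail were chosen after the results they bear on were seen, as were the splits within replicate numbers, and the test of shared counting noise was added after the recounting test. Transcripts with an AU-rich element, the sequence bound by decay factors such as ZFP36L2, were lost faster. Within bins of 3' UTR length and GC content, genes with TATTTAT in the 3' UTR (3962 of 10619) had a median slope lower than others by a difference of -0.117 log2 per hour (permutation p = 5e-04, the smallest that 2000 permutations can give). The shuffled motifs TTATATT and TTTAATT gave -0.0273 (permutation p = 0.0545) and -0.0216 (permutation p = 0.115), and the second table gave -0.0680 for TATTTAT (permutation p = 5e-04, again the smallest). Longer coding sequences also went with faster relative loss across genes, which are not independent replicates: Spearman's rank correlation of coding length and slope was -0.218 (95% bootstrap interval -0.234 to -0.201) over 11504 genes, and -0.137 in the second table. That sequence features take part in decay is a hypothesis from the same data. The slope also went with 3' UTR length (rank correlation -0.253, and -0.101 in the second table), transcript length (-0.287 and -0.133) and GC content (0.241 and 0.0618). No test separated coding length from these.

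T lineage transcription factors were lost faster than housekeeping genes. Their median slope of -0.59 log2 per hour stood at percentile 0 of 10000 random lists matched on expression, transcript length and GC content, whose central 95% ran from -0.17 to 0.16, and at 0 in the second table too (-0.24 against -0.07 to 0.11), so these properties as measured do not account for it. Broadly expressed transcription factors stood at percentile 8.37, the m6A machinery at 0.07, T cell surface genes at 0.2, and KRAB zinc finger and immediate early genes at 0, so low percentiles were not particular to lineage factors. Housekeeping genes, the comparator, stood at 98.55, above the matched range. Fast decay of RNA of lineage factors stays as a hypothesis, since no spike-in or labelled RNA was analysed here and any residual transcription or change of decay by the drug itself was not tested.

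Ribosomal protein and oxidative phosphorylation transcripts lay higher at 120 min relative to the typical transcript. Their medians of 1.30 and 0.93 stood at percentiles 100 and 99.85 of random lists matched on expression and length (0.77 to 0.96 and 0.62 to 0.88). The matched lists themselves lay high, with medians of 0.88 and 0.76. How closely the drawn genes matched the length and expression of the members was not measured, and GC content was not matched. The test therefore cannot decide whether short length is the whole cause. Loss of other transcripts without any increase of these stays open: scaled to ribosomal protein counts, oxidative phosphorylation lay at -0.375, but the scaling itself sets that level. A rise and a slower loss cannot be told apart without a spike-in.

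Changes were smaller in the second table than in the first. In the median library 3.61% of 7345 well-covered genes had less than 0.5 times their first-table count in the second table. Library totals were larger in the second table, so a small share could arise whichever reads were counted. This share therefore cannot decide whether the same reads were counted again. The log ratio of the tables varied between replicates 7.41 times as much as independent counts would (95% interval 7.23 to 7.58, over 9586 genes). That spread argues against the same reads counted on another build. A constant background of reads may stay open: the ratio of the second to the first table's median change of well-expressed immediate early genes was 0.649, with an interval (0.536 to 0.880) that spans the bound set in advance, and 0.626 (0.209 to 0.939) for weakly expressed ones, where a background would shrink changes more. RNA without a poly(A) tail, from other libraries of the same samples, may also stay open: RMRP stood at 16893 CPM in the second table and 32.1 in the first, 526 times higher, and 23 replication histones were higher by a median of 286 times. Structural noncoding RNA took 15.6% to 32.2% of counts in the second table and 0.0032% to 0.0102% in the first, although the labels describe poly(A) RNA for all libraries.

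Splits of the same libraries were counted against the real one. For 15, 60 and 120 min the 10 splits of 6 libraries are too few for a share under 0.05; the real splits gave 29, 2926 and 5457 genes and the highest of the others 0, also among the 3 others that part every replicate pair, so 1 of 10 was as large. For lists at 120 min, again with 10 splits, the real one called 15 and the others from 8 to 14 (up to 13 among those that part every pair). The number of lists called therefore does not set the real split apart. Along time 1 of 100 splits, the real one, gave as many genes as the 6183 observed, and the highest other gave 2257. Of 100 splits within replicate numbers 1, the real one, was as large and the highest other gave 3884. The real times thus gave the most calls, a share under 0.05, though 1 of 100 is the smallest share that these splits can give. Only the number of calls was compared, not which genes were called.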
